A study of Mus musculus with 40 samples.

How the data were processed

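Gene expression was measured in 40 samples of mouse splenic B cells, 5 biological replicates in each of 8 groups formed by genotype (Bank1-/- or WT) and hours of CpG (0, 6, 24 or 48). Per the labels, the cells were enriched by negative selection on magnetic beads to a typical purity above 95% B220+CD3-, the Bank1-/- line had been backcrossed for 9 generations to C57BL/6, and 150 ng of total RNA per sample was amplified and biotin-labelled for Illumina arrays. The labels name both littermates and purchased C57BL/6J mice as a source of WT animals, without saying which gave the arrays. Groups and replicate numbers came from the sample labels.

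The authors deposited 2 tables. The first holds probe intensity on a linear scale, which per the file headers is not normalized. Its header announces detection p-values that the table does not hold, and 8 further columns, of a later time that matches no sample, were not used. The second is the authors' processed table of log2 intensity. Its processing is not stated per the labels, but from the values all columns share 1 distribution with a median of 6.87, each ranks its probes as the raw intensity does (Spearman correlation of 1), and it differs by at most 0.128 from a quantile normalization of the log2 intensity of the 40 arrays.

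From the deposited intensity, background was corrected by normexp with an offset of 50, arrays were quantile normalized and log2 was taken, with limma 3.58.1 in R 4.3.3. This was the setting fixed for a table without usable detection p-values, while control-based correction from those p-values had been the first choice. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. A probe was named through the platform annotation of 2016, updated through Entrez gene identifiers to the mouse reference annotation (GRCm38.p6). Of 45281 probes 34885 had 1 gene symbol, 18 several and 10378 none, and the update took 34807 symbols through the identifier and altered 0. A probe counted as detected on an array above the 99th percentile of 1287 probes of olfactory receptor genes, which B cells were taken not to express, and was kept if detected on at least 5 of 40 arrays. That left 18631 probes, 15530 with 1 symbol, and the probe with the highest mean per gene represented 9483 genes. No array reached the scanner maximum of 65535, the largest signal was 37276, and 0 pairs of arrays were identical. The mean raw signal per array was 145.7 to 539.9, with 10401 to 16768 probes detected, and precision is limited by the 5 arrays per group.

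Each gene was fitted with lmFit and eBayes on log2 values with 1 coefficient per group, all 40 arrays sharing 1 estimate of spread with 32 residual degrees of freedom. The 13 comparisons were Bank1-/- against WT at each time, each later time against 0 h within each genotype, and the difference of these responses between genotypes (Bank1-/- minus WT). Tests were two-sided, adjusted by the Benjamini-Hochberg method over 9483 genes, and called at an adjusted p under 0.05. Where a gene was not detected on any array of a group, its fold is given as a lower bound: the mean of the other group over the mean of, per array, the higher of the detection threshold and the probe's own value. No size is given for a difference of responses with such a group, and a list's median at the bound takes such genes at that bound, and at 0 between groups that both lack detection. All values come from this fit unless the setting is named.

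In addition, 24 gene lists were tested. They held interferon-inducible, NF-kB and early Toll-like receptor, p38, MNK and eIF4E, cytokine, cell cycle, plasma cell, mature B cell, marginal zone, receptor signalling, ribosome biogenesis, glycolysis, cholesterol, integrated stress response, apoptosis, and immediate early and heat shock genes. Others held markers of T cells, NK cells, myeloid cells, dendritic cells, erythroid cells, platelets, sex and strain (Nnt) and the genes within 10 Mb of Bank1. For each list the members past the threshold were counted over all genes and adjusted over the list alone, and the list was compared with all other genes by camera with a preset correlation of 0.01. Camera was repeated with an estimated correlation, and p-values were adjusted over lists within a comparison. Where the text gives no p with an estimated correlation beside a camera call, the call held with it. Fry, which tests whether the genes of a list move on balance 1 way, gave the interferon-inducible list an adjusted p of 2.2e-11 at 6 h between genotypes. The correlation across genes of responses in the 2 genotypes used different libraries for each.

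The comparisons, the fit, the lists and the rule for named genes were chosen before the data were examined. The rule named Bank1, Il6 and Nnt, the 10 largest rises and 10 largest falls between genotypes, the 8 largest rises and falls at each WT time, the 5 smallest p of each difference in response, and up to 4 members with the smallest p of a list described in a comparison, clone names left out. Genes near Bank1 that were called at more than 1 time were singled out after their values were seen. The detection rule, list medians at the bound, the olfactory receptor probes as controls for the background, array brightness (centred log2 mean signal) and the erythroid list mean as covariates, and the fits without the library labelled Bank1-/- 0 h replicate 5 were chosen after the data were seen. The other settings tried, chosen in advance, were log2 with quantile normalization alone, the authors' table, no detection filter, detection on all 5 arrays of a group, every detected probe counted, array weights, the replicate number as a block, fits of the compared groups alone, a fold threshold of 1.5, and each array left out in turn.

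The fit was tested on simulated arrays made from the 9483 genes with known changes. For Bank1-/- against WT it recovered 68.8%, 62.5%, 56.2% and 65.6% of genes changed by 0.585 on the log2 scale (1.5-fold) at 0, 6, 24 and 48 h, between 90.8% and 98.5% of those changed by 1, and 100% of those changed by 2, with 3 to 10 false calls. The simulated noise was independent between genes and arrays, with the same spread on every array. It held no difference in brightness and no library apart, so the false calls in the real arrays may be more.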

Results

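Gene expression was measured on Illumina bead arrays in mouse splenic B cells that lacked Bank1 (Bank1-/-) or carried it (WT). Bank1 encodes a scaffold protein with ankyrin repeats that B cells use in receptor signalling. The cells were cultured for 0, 6, 24 or 48 h with CpG, bacterial-type DNA that activates B cells through Toll-like receptor 9. Each of the 8 groups held 5 biological replicates, so 40 arrays entered each fit for which no smaller number of groups or arrays is named. No group cultured without CpG was analysed here, so changes from 0 h combine CpG with time in culture and with any recovery from isolation of the cells. The title of the study names IL6, interferon-inducible genes, p38 signalling and the eIF4E initiation complex, and the comparisons of genotypes and times address these. The mean raw intensity of an array ran from 145.7 to 539.9, and between 10401 and 16768 of the 45281 probes were detected. The WT 6 h arrays were the dimmest group, with a mean signal of 254 ± 118 (SD, n = 5) against 420 ± 98 in Bank1-/- at 6 h. The number of arrays limits the precision of all values.

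Bank1 signal was lower in every Bank1-/- library than in every WT library of the same time, though it stayed detected in most of them. At 0 h its mean normalized log2 intensity was 9.42 ± 1.02 (SD, n = 5) in Bank1-/- and 11.26 ± 0.20 in WT, a log2 difference of -1.84 (SE 0.25, adjusted p = 1.3e-05). The differences were -0.996 at 6 h (adjusted p = 0.00487), -2.42 at 24 h (adjusted p = 6.0e-08) and -2.26 at 48 h (adjusted p = 3.5e-07). Without the library labelled Bank1-/- 0 h replicate 5 the 0 h difference was -1.39 (adjusted p = 3.0e-08), and a fit of the 0 h groups alone gave -1.84 with an adjusted p of 0.317. At 6 h, with an erythroid score as a covariate and the library labelled Bank1-/- 0 h replicate 5 left out, the difference was -0.39 (adjusted p = 0.23). A single probe measured Bank1, and its place relative to the deleted part of the gene is not given. Bank1 itself fell by 3.53 on the log2 scale in WT between 0 and 6 h (adjusted p = 7.3e-15), and its 48 h level in WT differed from that at 0 h by -0.11 (adjusted p = 0.741).

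Il6, which encodes the cytokine interleukin 6, was higher after 6 and 24 h of culture with CpG than at 0 h in both genotypes, and its difference between genotypes did not pass the test at any time. In WT it was not detected at 0 h and was at least 9.51-fold higher at 6 h (adjusted p = 6.7e-11), at least 12-fold higher at 24 h (adjusted p = 5.4e-11) and at least 2.72-fold higher at 48 h (adjusted p = 0.000207). In Bank1-/- the log2 rise was 3.41 at 6 h (adjusted p = 7.2e-11) and 2.67 at 24 h (adjusted p = 6.5e-08), and the 48 h difference was 0.51 (adjusted p = 0.214). The library labelled Bank1-/- 0 h replicate 5 was the 1 array of its group with detected Il6, so these values and those in WT are not on the same footing, and without it the 48 h difference passed as well (adjusted p = 5.4e-08). Between genotypes Il6 was at least 1.44-fold higher in Bank1-/- at 0 h (adjusted p = 0.361), and its log2 difference was 0.69 at 6 h (adjusted p = 0.145), -0.39 at 24 h (adjusted p = 0.659) and -0.40 at 48 h (adjusted p = 1). The 0 h value rested on that library, without which Il6 was detected in neither group. The 6 h value passed in 5 of the alternative fits, among them the fit without that library in the shared spread (adjusted p = 0.000889) and the fit with the erythroid list mean as a covariate, where it was 1.99 (adjusted p = 0.00357), or 0.42 (adjusted p = 0.259) when that library was left out as well. The 24 h value passed with array weights (-0.52, adjusted p = 0.011).

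**Figure D1:**
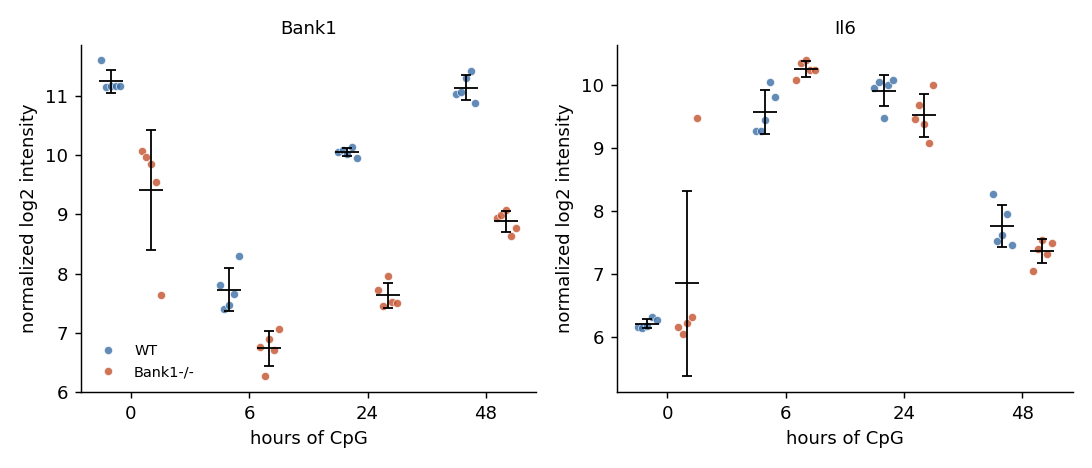
Normalized log2 intensity of Bank1 (left) and Il6 (right) against hours of CpG, with each point an array, blue for WT and orange for Bank1-/-, and black marks for the mean and SD of 5 arrays. Bank1 was lower in the Bank1-/- arrays at each time, and 1 array labelled Bank1-/- 0 h had an Il6 level of 9.48 while the other 4 lay between 6.05 and 6.31.

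The library labelled Bank1-/- 0 h replicate 5 stood apart from the other 4 of its group. Its Bank1 level was 7.64 and its Il6 level 9.48, and the erythroid gene Hba-a1, which encodes alpha globin, was at 6.17 where the other 4 lay between 8.46 and 9.99. Across the genes tested it lay at a root mean square log2 distance of 0.159 from the nearest Bank1-/- 24 h library and of 0.978 from the nearest other Bank1-/- 0 h library. Values at 0 h that include it may therefore not describe cells before CpG alone. The library was kept in the fit, and several values that rest on the Bank1-/- 0 h libraries are given without it as well.

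At 0 h, the stress and immediate early genes were lower in Bank1-/- than in WT B cells before CpG. Whether isolation of the cells, litter or source of the mice differed between the genotypes was not tested, so this difference cannot be assigned to Bank1. Hspa1a and Hspa1b, which encode the inducible heat shock protein Hsp70, differed by -3.29 (SE 0.39, adjusted p = 5.9e-07) and -3.07 (SE 0.39, adjusted p = 2.9e-06) on the log2 scale. Fosb and Fos, which encode parts of the AP-1 transcription factor, differed by -2.10 and -2.06. The other largest falls were in Bank1, Rgs1, a brake on G protein signalling, the histone gene H2bc4, Ppp1r15a, a regulator of the eIF2 phosphatase, Junb of AP-1 and the transcription factor gene Egr2, at -1.84 to -1.46. The largest rise was in Gbp2b, which encodes an interferon-inducible GTPase, at least 2.58-fold (adjusted p = 3.7e-11). Cd44, an adhesion receptor, rose by 1.17, Notch1, a receptor of cell fate decisions, by 0.99, the cytokine gene Il10 by 0.93 and Erdr1 by 0.80. Amy2a5 (an amylase), Zbtb32 (a repressor of transcription), Phf10 (a chromatin remodelling subunit), Sfxn1 (a mitochondrial serine carrier) and Xpot (an exporter of tRNA) rose by 0.78 to 0.93. Without the library labelled Bank1-/- 0 h replicate 5, Hspa1a differed by -2.50, Fosb by -1.55, Fos by -0.88, Rgs1 by -1.09, H2bc4 by -0.74, Ppp1r15a by -0.92, Egr2 by -0.68, Cd44 by 0.71, Notch1 by 0.66, Phf10 by 0.46 and Il10 by 0.51, all past the threshold, while Junb (-0.82, adjusted p = 0.0681) and Sfxn1 (0.52, adjusted p = 0.0778) were not.

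Of the 30 measured immediate early and heat shock genes, 13 fell and none rose at 0 h, and 24 fell when adjusted over the list alone. The median was -1.07 (camera adjusted p = 1.0e-31), and it was -0.60 without that library, where 13 also fell. Dnajb1, a partner of Hsp70, and Hspb1, a small heat shock protein, differed by -1.13 and -1.27. Of 37 NF-kB and early Toll-like receptor response genes, 4 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.18 (camera adjusted p = 4.9e-07) and -0.14 without that library. Rel, an NF-kB subunit, and Marcksl1 differed by -1.04 and -0.97, and by -0.63 and -0.71 without that library, where Marcksl1 did not pass (adjusted p = 0.118). Of 35 genes of the p38, MNK and eIF4E pathway, 3 fell and none rose (4 fell adjusted over the list alone; camera adjusted p = 0.0274; adjusted p = 0.261 with an estimated correlation). These were Eif4e, the cap-binding initiation factor (-0.76), Mapk12, a p38 kinase (-0.34), and Zfp36, a factor that speeds decay of cytokine mRNA (-1.28). The Eif4e signal in Bank1-/- lay near the background. Without that library Zfp36 was at -0.62, and the p38 phosphatase gene Dusp1, at -1.53 with it (adjusted p = 0.0654), passed at -0.62 (adjusted p = 0.00352).

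The lists of mature B cell identity and cell cycle genes at 0 h followed the same library. Of 41 mature B cell genes 1 fell, Fcrl1, a receptor on B cells (-0.74; -0.49 without the library, adjusted p = 0.108), and 10 fell adjusted over the list alone, with a median of -0.56 (camera adjusted p = 2.9e-15; adjusted p = 0.261 with an estimated correlation) that was -0.09 without the library. Btla, Cr2 and Cd72, other B cell surface receptors, were at -0.62, -0.60 and -0.82 without passing. None of 50 cell cycle genes passed, adjusted over the list alone or over all genes, and their median of 0.45 (camera adjusted p = 1.1e-07; adjusted p = 0.434 with an estimated correlation) became -0.03 without the library. Cdc45, Nusap1, Kif23 and Ccne2, which serve DNA replication and mitosis, were at 0.94, 0.86, 0.68 and 0.63, and none of these passed. Of 51 interferon-inducible genes 1 fell, both over all genes and adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.000602; adjusted p = 0.315 with an estimated correlation) and -0.02 without the library. The gene that fell was the GTPase gene Gbp3 (-0.71), which lies within 10 Mb of Bank1. By limma with all 40 arrays, 145 of 9483 genes passed at 0 h, 68 higher and 77 lower in Bank1-/- (46.9% higher). With the library labelled Bank1-/- 0 h replicate 5 left out 114 passed, 67 of them shared, a fit of the 2 groups alone called 3, and leaving out 1 array at a time gave 51 (without WT 0 h replicate 1) to 323 (without Bank1-/- 0 h replicate 2). The balance of directions turned in other fits, with 57.3% of 337 genes higher with array brightness as a covariate, 59.7% of 722 with array weights and 60.3% of 919 with the erythroid list mean as a covariate.

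**Figure D2:**
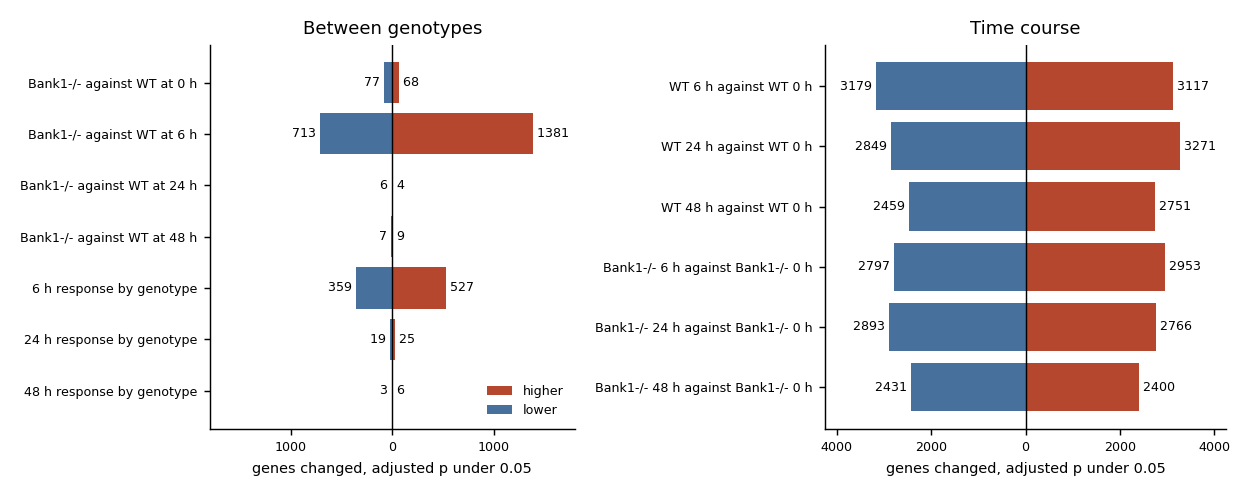
Number of genes with an adjusted p under 0.05 in each comparison of genotypes, of responses by genotype and of times, with bars to the right for genes that were higher and to the left for genes that were lower in the first-named group (for responses by genotype, in Bank1-/-). Between genotypes 145 genes passed at 0 h, 2094 at 6 h, 10 at 24 h and 16 at 48 h, while with array brightness as a covariate 337 passed at 0 h and 202 at 6 h.

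At 6 h, interferon-inducible genes were higher in Bank1-/- than in WT B cells. Of 51 measured members of the list 35 were higher and 1 was lower, over all genes and adjusted over the list alone, with a median log2 difference of 0.60 (camera adjusted p = 2.0e-17; adjusted p = 0.00444 with an estimated correlation), and of 0.50 with the 10 genes that had a group without detection at their bound. Ccl5, a chemokine gene, was 3.79-fold higher (log2 1.92, SE 0.16, adjusted p = 4.3e-11). Trim30a, an interferon-induced regulator of inflammatory signalling, was 3.84-fold higher (log2 1.94, SE 0.19, adjusted p = 1.6e-09). Apol7c, of the apolipoprotein L family, differed by 1.85, the GTPase genes Ifi47 and Gvin1 by 1.56 and 1.47, Phf11a by 1.47, and Usp18, which removes the ubiquitin-like ISG15 from proteins, by 1.56. Of the genes named here Trim30a, Ifi47 and Usp18 belong to the list. The list mean was at least 8.21 in the 5 Bank1-/- libraries and at most 7.78 in the 5 WT libraries. For 22 of the 51 genes all 5 Bank1-/- libraries lay above all 5 WT libraries. The share of all genes with such a separation was not computed, and 1381 of the 9483 genes were called higher at 6 h, so the count is descriptive. The WT arrays were dimmer, and with array brightness as a covariate 21 of the list's genes stayed higher and none lower, with a median of 0.53 (camera adjusted p = 2.5e-28). With the erythroid list mean as a covariate the interferon-inducible genes, Bank1-/- against WT at 6 h, had a median of 0.31 (camera adjusted p = 0.00905), and 0.66 when the library labelled Bank1-/- 0 h replicate 5 was left out as well. For these covariate fits camera used the preset correlation alone.

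**Figure D3:**
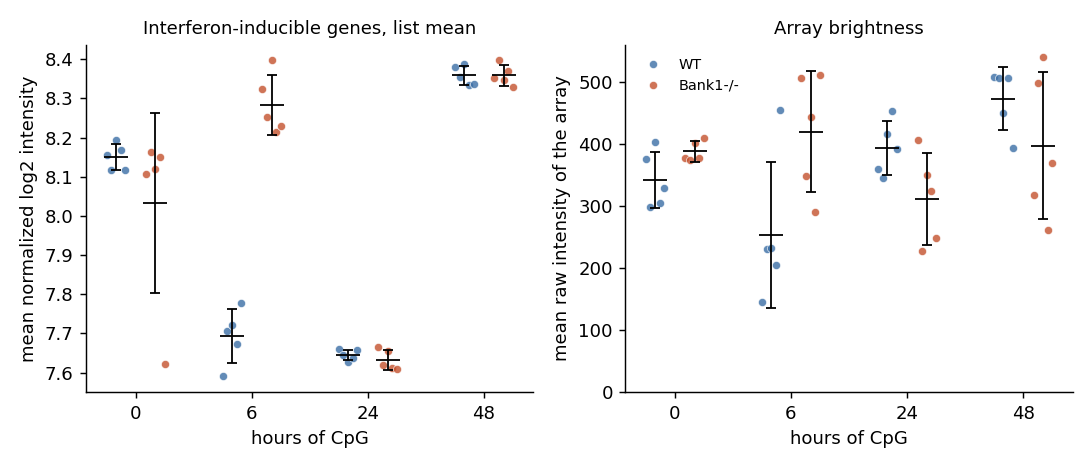
Mean normalized log2 intensity of the interferon-inducible genes (left) and mean raw intensity of the array (right) against hours of CpG, with each point an array, blue for WT and orange for Bank1-/-, and black marks for the mean and SD of 5 arrays. At 6 h the list mean was 8.21 or more in Bank1-/- and 7.78 or less in WT, and 4 of the WT arrays had a mean intensity of 145.7 to 231.9.

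Globin transcripts were also higher in Bank1-/- at 6 h, as was the erythroid marker Slc4a1. Hba-a1 and Hbb-bs, which encode the globin chains of haemoglobin, differed by 2.21 (SE 0.34, adjusted p = 2.3e-05) and 1.497 (SE 0.24, adjusted p = 4.5e-05). Of 5 erythroid markers 3 were higher and none lower, Slc4a1, the red cell anion exchanger, being the other (at least 1.07-fold, with no detection in WT). Adjusted over the list alone 4 were higher and 1 was lower, and the median was 0.68 (camera adjusted p = 0.0112; adjusted p = 0.0581 with an estimated correlation), or 0.10 with 2 markers at their bound. Sptb, a spectrin of the red cell skeleton, was detected on 1 Bank1-/- and no WT array (adjusted p = 0.0632). The list mean lay between 7.93 and 8.63 in the Bank1-/- libraries and between 7.26 and 7.59 in the WT libraries. Markers of other cells passed camera at 6 h in no list (T cells adjusted p = 0.626, NK cells 0.335, monocytes, macrophages and granulocytes 0.899, dendritic cells 0.56, platelets and megakaryocytes 0.704). Among the markers of each list, 0 and 2 of 6 T cell, 2 and 0 of 4 NK cell, 2 and 0 of 11 myeloid, 1 and 0 of 6 dendritic cell and 1 and 0 of 8 platelet genes were higher and lower. Of 3 sex-linked markers 2 were higher (camera adjusted p = 0.162). Adjusted over each list alone the counts were the same, except for none of the dendritic cell and 3 of the sex-linked markers.

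Among the 10 largest falls at 6 h were genes of RNA-binding and translation proteins, for which no list was tested. Eef2, the translation elongation factor, differed by -2.81 (SE 0.42, adjusted p = 1.6e-05), Ddx5, an RNA helicase, by -1.95, and Hnrnpk and Hnrnpa2b1, which bind nascent mRNA, by -1.68 and -1.65. Rbbp7 (a histone chaperone), Ctcfl (a DNA-binding factor), Srp54a (of the signal recognition particle) and Syngr2 differed by -1.87, -1.81, -1.505 and -1.502. ND5, a mitochondrially encoded subunit of complex I, differed by -1.99, and by 0.07 with array brightness as a covariate. Slirp, which binds mitochondrial mRNA, was higher by 1.47. Nnt, a mitochondrial transhydrogenase whose loss marks the C57BL/6J substrain, differed by -1.61 on 1 probe (adjusted p = 0.00259), but by 0.14 on its other detected probe, and by -0.30 with brightness as a covariate (adjusted p = 0.617). With that covariate Ctcfl was at -0.04, and Hnrnpk, Hnrnpa2b1, Srp54a and Syngr2, at -1.05, -1.25, -1.08 and -0.99, did not pass either.

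The gene lists around NF-kB and p38 had members on both sides at 6 h. Of 37 NF-kB and early Toll-like receptor genes 5 were higher and 4 lower, also adjusted over the list alone (median 0.14, camera adjusted p = 0.735). The transcription factor genes Irf1 and Myc stood at 1.47 and -1.302, Nfkbia, the NF-kB inhibitor, at -0.78 and Stat5a at -0.38, and all 4 passed. Of 35 genes of the p38, MNK and eIF4E pathway 4 were higher and 3 lower, also adjusted over the list alone (median -0.05, camera adjusted p = 0.335). Eif4e was at -1.13, Mknk1, a kinase of eIF4E, at -0.63, Eif4h at -0.40 and the RNA-binding Tial1 at 0.55. In all, 2094 genes passed at 6 h, 1381 higher and 713 lower, 774 of them by at least 1.5-fold. With array brightness as a covariate 202 genes passed, 186 of them shared, with array weights 3467 did, and with the erythroid list mean as a covariate 3052 did, 1103 of them shared. A fit of the 2 groups alone called 770, and leaving out 1 array gave 1234 (without WT 6 h replicate 1) to 3123 (without WT 6 h replicate 5).

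At 24 h, 10 genes differed between the genotypes, 4 higher and 6 lower in Bank1-/-. Eif4e was lowest after Bank1, at -1.83 (SE 0.14, adjusted p = 8.6e-12), with a mean of 6.27 ± 0.24 in Bank1-/- and 8.10 ± 0.09 in WT, and it was detected on 1 of the 5 Bank1-/- arrays. Max, the partner of Myc, differed by -0.84, Prdm16, a transcription regulator, differed by -0.73, Serpinb6b, a protease inhibitor, by -0.54 and Manba, the lysosomal beta-mannosidase, by -0.47. Erdr1 was higher by 0.85, Ddit4, a stress-induced inhibitor of mTORC1, by 0.85, Pafah1b3, of an acetylhydrolase of lipids, by 0.72 and Zcwpw1, a reader of histone marks, by 0.57. None of 51 interferon-inducible genes passed over all genes, and adjusted over the list alone 1 was lower (median -0.01, camera adjusted p = 0.871). None of 26 glycolysis and hypoxia genes passed, 3 were higher adjusted over the list alone, and their median was 0.16 (camera adjusted p = 2.1e-05; adjusted p = 0.903 with an estimated correlation). Egln3 and Pdk1, which are induced in hypoxia, were at least 1.40-fold higher (with no detection of Egln3 in WT) and at 0.62, Ankrd37 at 0.96 and P4ha1 at 0.28, none of which passed. With array brightness as a covariate 6 genes passed, Pafah1b3, Max, Prdm16 and Manba no longer among them, and with array weights 1758 did. Without the library labelled Bank1-/- 0 h replicate 5 in the shared spread 34 passed, and a fit of the 2 groups alone called 16. Leaving out 1 array at 24 h gave 5 (without Bank1-/- 24 h replicate 5) to 14 (without Bank1-/- 24 h replicate 3).

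At 48 h, 16 genes differed, 9 higher and 7 lower in Bank1-/-. Gbp2b was highest, at 1.59 (SE 0.13, adjusted p = 1.2e-10), and its relative Gbp2 was lower, at -0.997 (SE 0.21, adjusted p = 0.0288). Eif4e was again lower, at -0.76 (adjusted p = 0.00298), as were Erdr1 (-1.21), Auts2 (-0.58) and App, the amyloid precursor gene (-0.45). Csprs and Pisd-ps3 were higher by 0.97 and 0.91, Agrn, the matrix protein agrin, by 0.71, Slc4a8, a bicarbonate transporter, by 0.61, and Tgm2, a transglutaminase, by 0.52. Rap1gap2, Scamp1 and Ret, a receptor tyrosine kinase, were higher by 0.48, 0.45 and 0.43. Among 51 interferon-inducible genes 1 was lower and none higher, and 2 were lower adjusted over the list alone (median 0.04, camera adjusted p = 0.804). The gene that passed over all genes was Gbp2, which lies within 10 Mb of Bank1. None of 29 genes of the integrated stress response and ATF4 passed, nor adjusted over the list alone (median 0.11, camera adjusted p = 0.00451; adjusted p = 0.271 with an estimated correlation). Its members with the smallest p, Ddit4, Atf3 (a stress-induced transcription factor) and the tRNA synthetase genes Mars1 and Gars, were at 0.47, 0.30, 0.38 and 0.25. With olfactory receptor probes as controls for the background 9 genes passed, 33.3% of them higher against 56.2% otherwise, and with array brightness as a covariate Slc4a8 and Scamp1 did not pass (adjusted p = 0.0922 for both). Without the library labelled Bank1-/- 0 h replicate 5 in the shared spread 28 passed, without Bank1-/- 48 h replicate 5 10 did, and with array weights 56.

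Several genes that differed at more than 1 time lie near Bank1 on chromosome 3. In the reference annotation (GRCm38.p6, used for gene order only), 46 measured genes lie within 10 Mb of Bank1. Eif4e was lower at all 4 times, Gbp2b was higher at 3 and at 0.57 at 24 h (adjusted p = 0.0813), Manba was lower at 6 and 24 h, and Gbp2 at 6 and 48 h. At the other times Manba stood at -0.35 at 0 h (adjusted p = 0.0681) and -0.31 at 48 h (adjusted p = 0.847). Gbp2 stood at -0.14 at 0 h (adjusted p = 0.81) and -0.84 at 24 h (adjusted p = 0.182). The 0 h value rested on the library labelled Bank1-/- 0 h replicate 5, where Gbp2 was at 6.83. It lay at 8.55 to 9.14 in the other Bank1-/- 0 h libraries and at 8.58 to 8.76 in WT at 0 h. Without that library the response of Gbp2 by limma differed by -1.12 at 24 h (adjusted p = 1.4e-07) and by -1.28 at 48 h (adjusted p = 4.6e-09). Gbp3 was lower at 0 h (-0.71), higher at 6 h (0.89) and at -0.49 at 48 h (adjusted p = 0.731). Gstcd was higher at 6 h (1.03) and Trmt10a, a tRNA methyltransferase, at 0 h (0.54). Over the 46 neighbours 2 were higher and 2 lower at 0 h, 8 and 6 at 6 h, none and 2 at 24 h, and 1 and 2 at 48 h. Adjusted over the list alone these were 3 and 3, 9 and 7, 1 and 6, and 1 and 4. The medians were 0.03, 0.06, -0.08 and -0.09 (camera adjusted p = 0.866, 0.961, 0.12 and 0.0307), and the last had an adjusted p = 0.514 with an estimated correlation. Eif4e and Gbp2b were each read by 1 probe, and the signal of Eif4e in Bank1-/- and of Gbp2b in WT lay near the background.

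**Figure D4:**
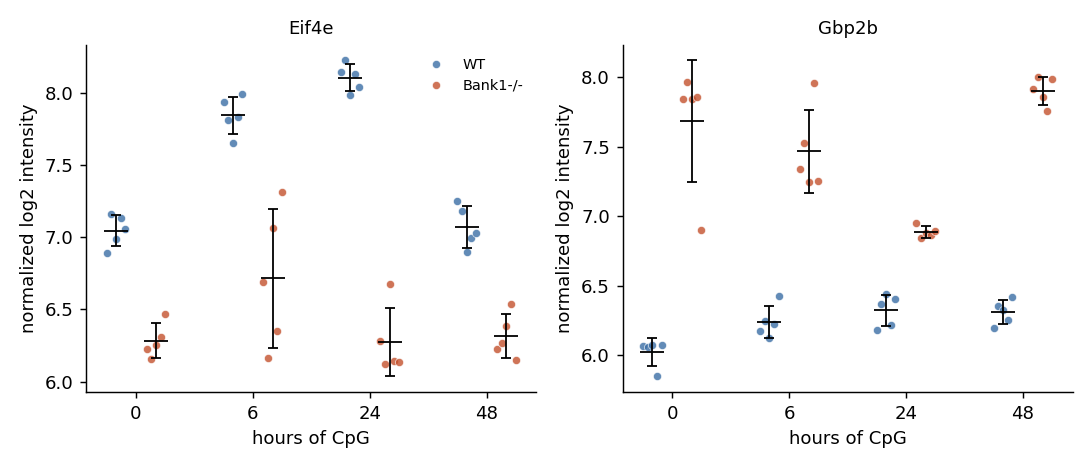
Normalized log2 intensity of Eif4e (left) and Gbp2b (right) against hours of CpG, with each point an array, blue for WT and orange for Bank1-/-, and black marks for the mean and SD of 5 arrays. Eif4e was lower in Bank1-/- at each time, by 1.83 on the log2 scale at 24 h (a difference of -1.83), and Gbp2b was at least 2.58-fold higher at 0 h, where it was detected on no WT array. The signal of Eif4e in Bank1-/- lay near the background, so the size of its difference is uncertain.

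In WT B cells, genes of ribosome assembly were higher and immediate early, heat shock and mature B cell genes lower after 6 h of culture with CpG than at 0 h. Slc7a3, an importer of arginine and lysine, was at least 25.8-fold higher (adjusted p = 2.7e-14). Batf, an AP-1 family transcription factor, rose by 4.57, Srm, the spermidine synthase, by 4.42, and Fdps of the sterol pathway by 4.08. Dctd and Dctpp1 of nucleotide metabolism rose by 4.06 and 3.70, and the receptor genes Plxnd1 and Ifnlr1 by 3.73 and 3.71. Hspa1b, Hspa1a and Fos were at -6.80, -6.46 and -6.45, Dusp1 at -5.78, the histone genes H1f2 and H2bc4 at -6.06 and -5.36, Sla, an adaptor that damps receptor signals, at -5.13, and the chemokine receptor gene Cxcr4 at -4.95. Of 40 ribosome biogenesis genes 38 rose and none fell, also adjusted over the list alone (median 1.86, camera adjusted p = 1.2e-15; adjusted p = 0.108 with an estimated correlation), with Noc2l at 2.29, Rrp9 at 2.71, Grwd1 at 2.45 and Wdr74 at 2.25. Of 41 mature B cell genes 36 fell and 1 rose, and 37 and 1 adjusted over the list alone (median -1.88, camera adjusted p = 2.1e-08; adjusted p = 0.483 with an estimated correlation). Fcrla, Ets1, the inhibitory receptor gene Cd22 and its relative Siglecg were at -3.54, -3.53, -2.42 and -3.39.

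Signalling genes of B cells mostly fell at 6 h in WT, and several cytokine genes rose. Of 45 genes of B cell receptor and Toll-like receptor signalling 30 fell and 6 rose, also adjusted over the list alone (median -0.75, camera adjusted p = 6.0e-05; adjusted p = 0.483 with an estimated correlation). The kinase gene Btk was at -3.06, the inhibitory adaptor Dok3 at -4.61, Irak3, a brake on Toll-like receptors, at -2.46 and the calcium channel gene Itpr3 at -2.28. Of 30 immediate early and heat shock genes 22 fell and 5 rose, also adjusted over the list alone (median -2.06, camera adjusted p = 4.9e-07; adjusted p = 0.386 with an estimated correlation), with Dnajb1 at -2.13 and Hspb1 at least 2.64-fold lower. Of 37 NF-kB and early Toll-like receptor genes 19 rose and 11 fell (19 and 12 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0762). Stat5a, Gadd45b and Traf1 rose by 2.50, 2.66 and 2.23 and Irf1 fell by 3.10. Of 24 B cell cytokine and chemokine genes 13 rose and 7 fell (14 and 7 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.0821). Ebi3, a subunit of IL27 and IL35, rose by 3.41, Il1b by 2.62 and Tnf by 1.37, and Il16 fell by 3.23. Of 51 interferon-inducible genes 9 rose and 30 fell (10 and 30 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.0761), or -0.15 with 11 genes at their bound. Samd9l, Sp100 and Pml fell by 3.55, 3.08 and 2.67, and Ifitm3, which blocks virus entry, rose by 1.94. In all, 6296 genes passed, 3117 higher and 3179 lower.

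At 24 h in WT, genes of DNA replication and mitosis rose. Pclaf, Tyms, Mcm10 and Cdc6, all of DNA synthesis, rose by 4.46, 4.44, 4.37 and 3.88. Asns, which makes asparagine, rose by 4.56, Bcat1 of branched-chain amino acid metabolism by 3.85 and Batf by 4.11, and Slc7a3 was at least 16.5-fold higher. Fos was at least 91.6-fold lower, and Hspa1a, H1f2, Hspa1b, Egr3, Dusp1 and H2bc4 were at -6.27, -6.05, -6.02, -5.80, -5.49 and -5.29. Cd86, a costimulatory ligand on activated B cells, fell by 5.30. Of 50 cell cycle genes 46 rose and 2 fell, also adjusted over the list alone (median 2.28, camera adjusted p = 3.4e-15; adjusted p = 0.202 with an estimated correlation), among them Bub1b (3.68), Cdc45 (3.12), Mcm5 (3.07) and E2f1 (2.60). Of 28 cholesterol synthesis genes 21 rose and 3 fell, also adjusted over the list alone (median 0.95, camera adjusted p = 0.000335; adjusted p = 0.202 with an estimated correlation). Fdps, Sqle and Hsd17b7 of the pathway rose by 3.72, 2.50 and 2.18, while Abcg1, which exports cholesterol, fell by 2.29.

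Marginal zone and interferon-inducible genes mostly fell at 24 h in WT. Of 16 marginal zone B cell genes 11 fell and 4 rose, also adjusted over the list alone (median -1.39, camera adjusted p = 0.0124; adjusted p = 0.202 with an estimated correlation), with Dtx1 and Hes1, both of the Notch pathway, at -2.50 and -1.51, Cd1d1 at -2.02 and Tm6sf1 at -1.67. Of 51 interferon-inducible genes 27 fell and 5 rose, also adjusted over the list alone (median -0.34, camera adjusted p = 0.000189; adjusted p = 0.202 with an estimated correlation), with Trim25 at -2.75, Sp100 at -2.56, Samd9l at -1.64 and Gbp3 at -1.37. Of 29 genes of the integrated stress response 17 rose and 9 fell, also adjusted over the list alone (median 0.73, camera adjusted p = 0.118). Shmt2 and Mthfd2, mitochondrial enzymes of folate metabolism, rose by 1.93 and 1.99 and Ppp1r15a fell by 3.97. In all, 6120 genes passed, 3271 higher and 2849 lower.

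At 48 h in WT, genes of antibody secretion, glycolysis and cholesterol synthesis were above their 0 h level. Of 35 plasma cell and antibody secretion genes 22 rose and 4 fell, also adjusted over the list alone (median 0.78, camera adjusted p = 0.000206; adjusted p = 0.0701 with an estimated correlation). Xbp1, the transcription factor of the secretory programme, rose by 1.90, and Fkbp11 and Sel1l, which fold or remove proteins in the endoplasmic reticulum, by 1.47 and 1.18. Derl3 of the same compartment, not detected at 0 h, was at least 1.78-fold higher. Of 26 glycolysis and hypoxia genes 18 rose and 4 fell, and 20 and 4 adjusted over the list alone (median 1.05, camera adjusted p = 4.8e-05; adjusted p = 0.278 with an estimated correlation), with Aldoc at 4.21, Pgk1 at 3.63, Ankrd37 at 3.54 and Ndrg1 at 1.65. Of 28 cholesterol synthesis genes 21 rose and 3 fell, also adjusted over the list alone (median 1.41, camera adjusted p = 7.1e-06; adjusted p = 0.173 with an estimated correlation), with Mvd, Sqle, Hsd17b7 and Ebp at 2.50, 2.46, 2.41 and 1.41. Of 30 apoptosis regulators 17 rose and 6 fell, and 18 and 7 adjusted over the list alone (median 0.56, camera adjusted p = 0.00495), with the death receptor gene Fas at 1.33, Ccng1 at 1.54 and Casp4 at 1.15.

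Ribosome biogenesis genes had fallen below their 0 h level at 48 h in WT. Of 40 of them 24 fell and 1 rose, also adjusted over the list alone (median -0.64, camera adjusted p = 2.8e-06; adjusted p = 0.278 with an estimated correlation), with Pes1 at -2.61, Nop14 at -1.72, Mybbp1a at -1.65 and Heatr1 at -1.38. Of 51 interferon-inducible genes 20 rose and 8 fell, also adjusted over the list alone (median 0.22, camera adjusted p = 0.16), with Ifi27 at 1.16, Psmb9 at 0.89, Dhx58 at 0.88 and Oasl1 at -1.22. The largest rise was that of Rsph1, a radial spoke gene, at least 30.7-fold, and Pclaf, Birc5, Nusap1, Kif22 and Top2a, most of them of mitosis, rose by 4.25, 4.14, 3.797, 3.75 and 3.69. Wfdc21 rose by 3.74. Hspa1b and Hspa1a were at least 104-fold and 82.4-fold lower, Fosb at least 20.5-fold, and Fos, Dusp1, H1f2, Cd86 and Rgs1 were at -6.44, -5.26, -4.89, -4.75 and -4.44. In all, 5210 genes passed, 2751 higher and 2459 lower.

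In Bank1-/- B cells many of the same genes changed from 0 h in culture with CpG. Of 40 ribosome biogenesis genes 39 rose at 6 h, also adjusted over the list alone, with none lower (median 1.52, camera adjusted p = 6.5e-16; adjusted p = 0.101 with an estimated correlation), with Ebna1bp2 at 2.72, Rrp9 at 2.45, Polr1b at 2.30 and Noc2l at 2.03. Of 50 cell cycle genes 46 rose and 2 fell at 24 h, and 47 and 2 adjusted over the list alone (median 1.77, camera adjusted p = 1.8e-15; adjusted p = 0.275 with an estimated correlation), with Birc5, Top2a, Aurkb and Mcm2 at 3.26, 3.16, 2.66 and 2.23. Of 35 plasma cell genes 24 rose and 1 fell at 48 h, and 24 and 2 adjusted over the list alone (median 0.60, camera adjusted p = 7.2e-06), with Xbp1 at 1.62, Fkbp11 at 1.46, Derl3 at 1.18 and Sel1l at 1.05. Of 51 interferon-inducible genes 24 rose and 11 fell at 6 h, and 25 and 12 adjusted over the list alone (median 0.29, camera adjusted p = 0.0476; adjusted p = 0.701 with an estimated correlation). Ifitm3, Ifi35 and Isg15 rose by 2.79, 1.98 and 1.88 and Samd9l fell by 2.19. Without the library labelled Bank1-/- 0 h replicate 5 that list's median was 0.26 (camera adjusted p = 0.386). Without it the medians of the ribosome biogenesis, cell cycle and plasma cell lists were 1.75, 2.23 and 0.73. In all, 5750, 5659 and 4831 genes passed at 6, 24 and 48 h, and 6216, 6180 and 5614 without that library. The log2 changes from 0 h in Bank1-/- and WT correlated across genes at 0.915, 0.951 and 0.942 for the 3 times, over genes that are not independent replicates. At 6 h 4664 genes passed in both genotypes with the same sign and 55 with opposite signs.

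The change from 0 h to 6 h of culture with CpG, called the 6 h response, differed between the genotypes for interferon-inducible genes and for immediate early and heat shock genes. In the test of the difference between the 6 h responses, 29 of 51 interferon-inducible genes were higher in Bank1-/- and none lower, and 38 and 1 adjusted over the list alone (median 0.69, or 0.60 with 11 genes at their bound; camera adjusted p = 4.2e-21; adjusted p = 0.00129 with an estimated correlation). Over all genes, clone names left out, the 5 with the smallest p were Apol7c (1.67), Phf11a (1.56), Usp18 (1.67), Ifi27 (1.49) and Ccl5 (2.11), of which Usp18 and Ifi27 belong to the list. Trim30a and Ifi47, also of the list, stood at 2.21 and 1.32. Of 30 immediate early and heat shock genes 13 were higher and none lower, and 18 adjusted over the list alone (median 1.102, camera adjusted p = 1.1e-13; adjusted p = 0.0372 with an estimated correlation). Dnajb1, Hspa1a and Hspa1b of that list stood at 1.19, 3.34 and 3.29, Hspb1 (adjusted p = 1.5e-05) was detected in neither genotype at 6 h and is given no size, and the median of the list was 0.72 without the library labelled Bank1-/- 0 h replicate 5. For these genes the difference lay at 0 h: between genotypes the list's median was -1.07 at 0 h and 0.05 at 6 h (camera adjusted p = 0.704), and Hspa1a stood at -3.29 and 0.06. Nnt differed by -1.68 on 1 probe (adjusted p = 0.0404), and by -0.69 with array brightness as a covariate (adjusted p = 0.238). The 6 h response of Il6, which was not detected in WT at 0 h, did not pass (adjusted p = 0.957), and without that library, with Il6 undetected at 0 h in both genotypes, the difference passed (adjusted p = 0.0303). In all, 886 genes differed in their 6 h response, 527 higher and 359 lower in Bank1-/-. With array brightness as a covariate 156 did, 151 of them shared, with array weights 2827, a fit of the 4 groups alone called 58, and leaving out 1 array gave 412 (without WT 6 h replicate 1) to 1981 (without WT 6 h replicate 5).

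At 24 and 48 h immediate early and heat shock genes again had a different response by genotype. These comparisons used the same 0 h libraries as the 6 h one, and between genotypes the list's median was -0.06 at 24 h and 0.01 at 48 h (camera adjusted p = 0.854 and 0.975). At 24 h Dnajb1 (1.02), H2bc6 (1.22), Hspb1 (adjusted p = 0.000113), H2bc8 (adjusted p = 0.000335) and Gbp2b (adjusted p = 0.00177) had the smallest p, the last with the lower response in Bank1-/-, and 6 of 30 immediate early and heat shock genes were higher, with none lower (14 adjusted over the list alone). Hspa1a and Fosb of that list passed as well (adjusted p = 0.00379 and 0.00493). No size is given for Hspb1 and Fosb, detected in neither genotype at 24 h, H2bc8, not detected in WT at 24 h, Hspa1a, not detected in Bank1-/- at 24 h, and Gbp2b, not detected in WT at 0 h. The median was 0.99 (camera adjusted p = 9.4e-18; adjusted p = 0.0199 with an estimated correlation). At 48 h Erdr1 (-2.01), Dnajb1 (1.17), Hspb1 (1.21, detected on 1 array of each genotype at 48 h), H2bc8 (adjusted p = 0.000249) and Hspa1a (adjusted p = 0.0011) had the smallest p, and 5 of the 30 genes were higher, with none lower (15 adjusted over the list alone; median 1.03, camera adjusted p = 1.3e-28; adjusted p = 0.00114 with an estimated correlation). Hspa1b passed as well (adjusted p = 0.00268), and H2bc8, Hspa1a and Hspa1b, detected in neither genotype at 48 h, are given no size. Without the library labelled Bank1-/- 0 h replicate 5 the list's medians were 0.51 and 0.61. In all, 44 genes differed at 24 h (56.8% higher) and 9 at 48 h (66.7% higher). Without that library these were 87 and 28, with array weights 1759 and 164 (39.7% and 53.7% higher), with the erythroid list mean as a covariate 247 and 220 (42.1% and 49.1% higher), and fits of the 4 groups alone called 22 and 5. Leaving out 1 array gave 23 (without WT 0 h replicate 1) to 152 (without Bank1-/- 0 h replicate 4) at 24 h and 8 (without Bank1-/- 48 h replicate 4) to 28 at 48 h. The responses of Bank1 (-0.58 and -0.42) and Il6 (adjusted p = 0.326 and 0.685) did not pass at 24 or 48 h, but without that library Bank1 differed by -1.03 at 24 h (adjusted p = 0.00498).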

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

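The tests of a wrong time label and of a swap for the library labelled Bank1-/- 0 h replicate 5, and those of a donor segment, of a probe variant and of the size of differences under brightness for the neighbours of Bank1, were chosen after the result was seen. Within groups of 5, a library was singled out when its gap to the nearest other exceeded 0.71 of the group's range, which chance gives in about 1 of 20 groups.

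The library labelled Bank1-/- 0 h replicate 5 lay far from the other 4 of its group for Bank1 (7.64 against 9.55 to 10.08), Il6 (9.48 against 6.05 to 6.31) and the mean of the interferon-inducible genes (7.62 against 8.11 to 8.16). Of 92 named genes 47 had a library apart in Bank1-/- at 0 h, 42 of them this one, and 14 of 17 list means did, where chance would give 4.6 genes. In the other groups the genes and list means with a library apart were 2 and 1 (Bank1-/- 6 h), 3 and 0 (Bank1-/- 24 h), 5 and 2 (Bank1-/- 48 h), 8 and 2 (WT 0 h), 11 and 3 (WT 6 h), 4 and 1 (WT 24 h) and 5 and 4 (WT 48 h). Single values apart were Bank1 in WT 0 h replicate 1 (11.61 against 11.16 to 11.17), Il6 in WT 24 h replicate 3 (9.47 against 9.94 to 10.08) and the mean signal of WT 6 h replicate 5 (455.1 against 145.7 to 231.9).

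A swap with a library labelled 24 h is argued against, since 0 of those lay nearer the 0 h mean. A wrong time label may explain the pattern, since the profile of the library lay with those of the 24 h libraries. On the axis from the other Bank1-/- 0 h libraries (0) to the Bank1-/- 24 h libraries (1) the library lay at 0.946, the 24 h libraries at 0.927 to 1.03 and the other 0 h libraries at -0.02 to 0.13. Its distance to the nearest Bank1-/- 24 h library was 0.159 (root mean square log2), against 0.165 for the closest pair of those and 0.978 to the nearest other Bank1-/- 0 h library. A mixture of 0 h and 24 h cells cannot be told apart: over 22 genes at least 16-fold higher at 0 h the library kept 2.97% of the 0 h signal and the 24 h libraries 1.76% to 2.47%, which passed the bound set in advance by less than the 24 h libraries' own range. That allowance for spread was added after the value was seen, and a first computation by another measure had given 0.32% against 0.28% in the highest 24 h library.

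For the interferon-inducible genes between genotypes at 6 h array brightness is argued against, since slopes from the 30 arrays of the other times predicted a median of -0.028 where 0.60 was observed (0.01 without the library labelled Bank1-/- 0 h replicate 5). Erythroid RNA cannot be told apart from genotype for these genes, since the erythroid means at 6 h did not overlap (7.931 to 8.627 in Bank1-/-, 7.265 to 7.589 in WT). With the erythroid mean as a covariate the median was 0.31, just above the bound of 0.5 of its value set in advance, and 0.66 without that library. This adjustment rests on slopes within groups, carried over to the gap between them. Bank1-/- 0 h replicate 4 had the highest erythroid mean of the 0 h libraries (7.73). Its interferon-inducible mean was 8.15, within the 8.11 to 8.16 of replicates 1 to 3. It is 1 array at 0 h, with an erythroid mean below all Bank1-/- 6 h libraries, so it does not decide the question at 6 h. For the number of genes between genotypes at 6 h (2094) brightness cannot be told apart from genotype: the predicted differences had a slope of 0.267 on the observed ones and the same sign for 85.7% of genes, and the arrays differed by 0.80 in log2 brightness. Erythroid RNA also stays open for that number, since with the erythroid mean as a covariate 3052 genes passed, 1103 of them shared with the 2094 (3536 and 1193 without that library). A difference of genotype in interferon-inducible genes may remain, as a hypothesis, and differences in culture, litter or source of the mice at 6 h were not tested.

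Among genes called the same way at 2 or more times, 4 of 46 genes within 10 Mb of Bank1 and 20 of 9436 others appeared (one-sided Fisher p = 4.8e-06, odds ratio 44.7). A donor strain segment that stayed around Bank1 after backcrossing may explain this and could not be separated from an effect of Bank1 on its neighbours. Array brightness as the source of the differences is argued against: with it as a covariate the 11 called differences of these 4 genes kept 92.4% to 113.7% of their size. Only 2 of the 4 genes (and 6 of the 20) stayed called at 2 or more times, since 3 calls ended (Manba at 6 h, -0.33 to -0.36, SE 0.102 to 0.122, and at 24 h, -0.47 to -0.45, SE 0.102 to 0.106, and Gbp2 at 6 h, -0.83 to -0.84, SE 0.214 to 0.26) with a larger SE and adjusted p. A sequence variant under a probe cannot be told apart either: a further detected probe existed for Manba alone, and at 0 of 4 times did it show the opposite direction.

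The change from 0 h in culture with CpG, called the response, differed between genotypes, by a test of the difference itself, for 886 genes at 6 h, 44 at 24 h and 9 at 48 h, and all 3 tests used the same 0 h libraries. For the immediate early and heat shock genes the genotypes differed at 0 h (median -1.07) and the medians at 6, 24 and 48 h were 0.05, -0.06 and 0.01. Isolation of the cells, litter and source of the mice were not tested as causes of the 0 h difference. The median differences were 0.70 for interferon-inducible genes at 6 h, and 1.102, 0.99 and 1.03 for immediate early and heat shock genes at 6, 24 and 48 h. For the immediate early and heat shock genes, the 0 h median and all 3 response medians were smaller in size without the library labelled Bank1-/- 0 h replicate 5. The values without it are given in the Results, and the sizes in this paragraph include it. At 6 h Apol7c differed by 1.67, Phf11a by 1.56, Usp18 by 1.67, Ifi27 by 1.49, Ccl5 by 2.11, Trim30a by 2.21, Ifi47 by 1.32, Dnajb1 by 1.19, Hspa1a by 3.34 and Hspa1b by 3.29. At 24 h Dnajb1 differed by 1.02 and H2bc6 by 1.22, and at 48 h Erdr1 by -2.01, Dnajb1 by 1.17 and Hspb1 by 1.21 (detected on 1 array of each genotype at 48 h). Other responses differed by limma with no size given, since at least 1 of the 4 groups had no detection: Hspb1 at 6 h (adjusted p = 1.5e-05), Hspb1, H2bc8, Gbp2b, Hspa1a and Fosb at 24 h (adjusted p = 0.000113, 0.000335, 0.00177, 0.00379 and 0.00493) and H2bc8, Hspa1a and Hspa1b at 48 h (adjusted p = 0.000249, 0.0011 and 0.00268).

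In each comparison at most 3 of 100 splits of the libraries, the real one included, gave as many genes, under the share of 0.05 set in advance. The shares were not adjusted for the 13 comparisons. At 0 h, at 6 h and for the 6 h response other splits exceeded the real count, so chance is argued against only weakly there and is not excluded. Between genotypes the real counts and the highest of the other splits were 145 and 536 at 0 h (3 of the 100 as large), 2094 and 3308 at 6 h (3 as large), 10 and 0 at 24 h (1) and 16 and 1 at 48 h (1). Which libraries the split with 536 genes at 0 h set apart, and why, was not examined. For the responses in WT they were 6296 and 4805, 6120 and 3551, and 5210 and 2574, in Bank1-/- 5750 and 5127, 5659 and 5637, and 4831 and 4654, and for the differences of responses 886 and 1747 (2 as large), 44 and 3, and 9 and 8.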

How the results depend on the processing

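Array brightness or the erythroid mean as a covariate, olfactory receptor probes as controls, and leaving the library labelled Bank1-/- 0 h replicate 5 out of the shared spread were chosen after the results were seen. The dim WT 6 h arrays limit the 6 h comparisons, and Il6 was not detected in WT at 0 h, so its values at 0 h and of its responses are fitted values and not sizes. Of 320 named results 318 kept direction and side of the threshold with the authors' values, 317 with log2 and quantile normalization alone, 301 without a detection filter, 296 with array weights, 291 with brightness, 296 with olfactory receptor controls and 278 in fits of the compared groups alone, and 3363 of 3540 with 1 array left out. The normexp alternative without controls was identical to the setting used, and control-based correction by detection p-values, a sex covariate and a slide block could not be run. Replicate numbers were not taken as pairs, since in none of the 10 pairs of groups was every same-number correlation over 0.1 (-0.4 to 0.418 over all) or every library closest to its own number. All 4 between Bank1-/- 0 and 48 h were above 0 (0.092 to 0.284, mean 0.152 against -0.025 for other numbers), and 3 of 4 Bank1-/- 6 h libraries were closest to their own number at 0 h. A replicate block gave 135, 2011, 7 and 15 genes between genotypes. The cause was not tested except for fits of fewer samples, a fold threshold and counts of more probes.

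Different 48 h responses numbered 14 with log2 and quantile normalization alone and 14 with the authors' values. Without a detection filter the chromosome 3 neighbours at 6 h had a median of 0. Array weights gave 722, 3467, 1758 and 56 genes between genotypes at 0, 6, 24 and 48 h, 2827, 1759 and 164 different responses, Il6 -0.057, 0.757 and -0.522 at 0, 6 and 24 h, and at 0 h interferon-inducible genes 0.001, cell cycle genes -0.008, neighbours -0.007 and Nnt -0.142.

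Brightness as a covariate gave 337, 202 and 6 genes at 0, 6 and 24 h, 156 and 26 different 6 and 24 h responses, NF-kB genes -0.038, neighbours -0.015 and ND5 0.073 at 6 h, interferon-inducible genes 0.025 at 24 h, Nnt -0.091 at 48 h and the 6 h response of Il6 -0.04. With the library labelled Bank1-/- 0 h replicate 5 also left out it gave 314 and 478 genes at 0 and 6 h, 241 and 31 different 6 and 48 h responses, at 0 h interferon-inducible genes -0.035, cell cycle genes -0.026, neighbours -0.022 and Il6 -0.036, at 6 h NF-kB genes -0.037, neighbours -0.008, Il6 0.626 and ND5 0.082, interferon-inducible genes 0.033 at 24 h and Nnt -0.093 at 48 h. Olfactory receptor controls gave 9 genes at 48 h, 24 different 24 h responses and -0.198 for the 6 h response of Il6.

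The erythroid covariate gave 919 genes at 0 h, 1592, 247 and 220 different responses, neighbours -0.001 and Nnt -0.079 at 0 h, NF-kB genes -0.172 and Il6 1.992 at 6 h, Bank1 0.148 in WT at 48 h against 0 h and Il6 -0.422 in Bank1-/- at 48 h against 0 h. With that library also left out it gave 583, 3536, 31 and 29 genes, 2979, 595 and 189 different responses, at 0 h interferon-inducible genes -0.003, p38 genes 0.109, Il6 -0.11 and Nnt -0.395, and at 6 h Bank1 -0.389, p38 genes 0.26 and Eif4h 0.019. That library out of the shared spread gave Il6 0.686 (adjusted p = 0.000889) at 6 h and 34 and 28 genes at 24 and 48 h. Fits of the compared groups alone gave 3, 770 and 16 genes at 0, 6 and 24 h, Bank1 -1.838 at 0 h (adjusted p = 0.317), Il6 0.686 at 6 h (adjusted p = 0.024) and 58, 22 and 5 different responses.

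Counting every detected probe gave 273 and 4407 at 0 and 6 h, 11943, 11355 and 9299 for WT times, 10655, 10479 and 8655 for Bank1-/- times and 1795, 93 and 33 different responses. At least 1.5-fold gave 82, 774 and 10 genes at 0, 6 and 48 h, 3986 and 3125 for WT at 24 and 48 h and 3733, 3464 and 2820 for Bank1-/- times. Leaving out 1 array gave 51 to 323, 1234 to 3123, 5 to 14 and 10 to 16 genes between genotypes, 412 to 1981, 23 to 152 and 8 to 28 different responses, interferon-inducible genes -0.131 to -0.018 at 0 h and -0.017 to 0.012 at 24 h, Il6 -0.023 to 0.834 at 0 h, cell cycle genes -0.031 to 0.591, neighbours -0.009 to 0.053 and Nnt -0.054 to 0.125 at 0 h, p38 genes -0.075 to 0.026 at 6 h and the 6 h response of Il6 -0.148 to 0.709.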

Other observations

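Erdr1, singled out after its values were seen, was called between genotypes at all 4 times with alternating direction, at 0.80, -1.14, 0.86 and -1.21, and its other probe stood at 0.69, -0.77, 0.82 and -0.51.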
